A study of Homo sapiens with 22 samples.

How the data were processed

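RNA-Seq of total RNA and Ribo-Seq of ribosome-protected fragments were measured in LN308 cells, with 11 libraries per assay on an Illumina NextSeq 500. The deposited files hold counts, whole numbers of reads per gene in each library, for 58278 Ensembl gene entries, and no other unit was used. STAR 2.5.4b, HTSeq and DESeq2 are named with genome build GRCh38, per the submitters' processing notes. Their roles, the gene annotation, the features counted and the strand setting are not given in the sources used here. Reads of overlapping and antisense genes therefore cannot be told apart, and values of pseudogenes and repeat copies are uncertain. For Ribo-Seq, cells were treated with cycloheximide at 0.1 mg/ml for 5 min, and 27 to 33 nt fragments of 80S monosomes were taken, per the labels' protocols; this drug can shift ribosomes along mRNAs, and gene counts hold no positions with which to look for it.

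Symbols were found for 57437 of the 58278 entries in the reference tables and 841 stayed as identifiers; 45 base identifiers occurred more than once and their entries were kept apart. Groups and replicate numbers came from the labels. The thapsigargin Ribo-Seq labels carry no replicate number, and these libraries were left out of fits with a replicate block. No pair of libraries held equal values: the chi-square per degree of freedom between libraries of 1 group was 28.7 to 636.

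Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr on the groups (minimum count 10), scaled by trimmed mean of M-values (TMM) and fitted with glmQLFit (robust) over all groups of an assay, and contrasts were tested with glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method over 41130 genes in RNA-Seq, 19411 in Ribo-Seq and 18500 in the joint model, and a gene was called at an adjusted p under 0.05. With no change, 2056, 971 and 925 genes would have an unadjusted p under 0.05. The biological coefficient of variation was 0.506, 0.546 and 0.426. Levels are TMM-scaled CPM, as mean ± SD over the libraries of a group, and fold changes are log2 values ± SE. Translational efficiency, the change in footprints beyond the change in RNA, was tested as an interaction in 1 edgeR model over both assays. Each thapsigargin group had 1 library, so its tests borrowed the spread of the other groups and assumed that the lone library varied like them; they have no replicate check.

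The comparisons, tests, alternatives, gene lists and naming rule were set before the data were examined; alternatives added later are named as such. The 27 lists hold 613 entries, of which 611 were matched; 2 histone genes (H3C2 and H3C3) were not. They were ER chaperones and folding, ER-associated degradation, ER translocation and vesicle traffic, N-glycosylation and hexosamine pathway, UPR sensors and transcription factors, PERK-ATF4 targets, amino acid synthesis and transport, cytosolic tRNA synthetases, one-carbon and folate metabolism, cholesterol synthesis, IRE1-dependent decay substrates, mRNAs with regulatory uORFs, ribosomal proteins, translation factors with TOP mRNAs, immediate early genes, ER stress apoptosis, autophagy, cytosolic heat shock, proteasome, cell cycle and DNA replication, p53 targets, mitochondrially encoded mRNAs, replication-dependent histones and extracellular matrix, and markers of glial, blood and epithelial cells. Lists with at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation.

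Named genes are, per tunicamycin comparison with untreated cells, the 8 highest and 6 lowest log2 fold changes among called genes with a mean of at least 50 counts and CPM that did not overlap between groups, the 3 members with the smallest p of each list that passed, and 10 sentinel genes. For 6 h against 2 h and for thapsigargin the 5 highest and 5 lowest were taken. Genes with no symbol are passed over in the text unless they are among 5 or fewer calls. Other genes are named where a list holds 5 or fewer calls, and these were chosen after their values were seen. Genes named in that way were not followed through the alternatives.

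Fits were tested on simulated counts, with 67, 67 and 66 genes changed 2-fold, 4-fold and 8-fold between tunicamycin at 6 h and untreated cells. In RNA-Seq (35689 genes) 5.97%, 64.2% and 98.5% of the changed genes were called, in Ribo-Seq (17858 genes) 7.46%, 76.1% and 92.4%, and for translational efficiency (16451 genes) 1.49%, 44.8% and 92.4%, with 5, 2 and 6 unchanged genes called. These shares cover simulated genes only, and are not the power over all tested genes of these libraries. Before fits were compared, replicate numbers were checked for pairing by the correlation of same-numbered libraries' deviations from their group means. Every pair was over 0.1 for RNA-Seq untreated and tunicamycin 6 h (0.109 to 0.226), RNA-Seq 2 h and 6 h (0.414 to 0.676), and Ribo-Seq untreated and 2 h (0.212 to 0.242), untreated and 6 h (0.122 to 0.196), and 2 h and 6 h (0.211 to 0.407). The alternatives were DESeq2 1.42.0, its size factors in edgeR, library size alone, no filter, a minimum count of 50, a filter on the 3-library groups, the compared groups alone, the replicate block, each library left out in turn and, for translational efficiency, limma voom and separate fits per assay. In the separate fits, genes with no usable standard error were kept with a p of 1. The filter on the 3-library groups, the fits without untreated replicate 1 of both assays or with the block besides, and those on replicates 2 and 3 alone were chosen after seeing the data. Leaving that library out of 1 assay was set before. The package data.table (version 1.17.8) handled the tables, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

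A count of 0 allows up to 3 counts, which is 0.0180 to 0.0296 CPM in RNA-Seq and 0.103 to 0.684 CPM in Ribo-Seq. These floors cover counting error only. Frame, footprint length and position along the mRNA were not analysed here, so upstream open reading frames were not measured.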

Results

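LN308 is an established glial cell line derived from an astrocytoma and lacking p53, per the labels. The cells received tunicamycin at 2.5 µg/ml, an inhibitor of N-linked glycosylation, or thapsigargin at 200 nM, an inhibitor of the SERCA calcium pump of the endoplasmic reticulum (ER). RNA levels (RNA-Seq) and ribosome-protected mRNA fragments (Ribo-Seq, which samples mRNAs under translation) were sequenced at 0 h, 2 h and 6 h. Each assay had 3 untreated libraries, 3 libraries of tunicamycin at 2 h, 3 at 6 h, and 1 thapsigargin library at each time. The 0 h libraries are labelled untreated although the protocol names a DMSO control, and no vehicle control of 2 h or 6 h was used here. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

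RNA-Seq totals were 138, 122 and 101 M counts (M, mega) in untreated replicates 1, 2 and 3, and 131, 119 and 109 M after 2 h of tunicamycin. They were 167, 115 and 117 M after 6 h, and 115 and 145 M after 2 h and 6 h of thapsigargin. Ribo-Seq totals were lower, at 29.2, 8.48 and 9.77 M in the untreated replicates, and 13.04, 9.28 and 4.39 M after 2 h of tunicamycin. They were 6.92, 8.77 and 10.1 M after 6 h, and 7.66 and 6.38 M after 2 h and 6 h of thapsigargin.

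Several libraries stood apart. RNA-Seq untreated replicate 1 had counts in 53489 genes, against 38264 to 40331 in the other RNA-Seq libraries, and lay at -330 on the first principal component (47.7% of variance), against 16.3 to 47.7. In it 68.7% of 399 olfactory receptor genes had at least 10 counts, against 3.01 to 5.51% elsewhere, and its TMM factor was 1.46. On the second component (21.3%) the replicate 1 libraries of tunicamycin and both thapsigargin libraries lay at 61.1 to 116 and the others at 4.64 or below. The same 4 libraries had 0.443, 0.479, 0.587 and 0.492% of RNA-Seq counts in mitochondrially encoded mRNAs, against 1.06 to 1.61% in the others. In Ribo-Seq, RNU4ATAC took 4.58% of untreated replicate 1 and GLIS3 took 6.50% of tunicamycin 6 h replicate 3. On its first component (21.6%) tunicamycin replicate 1 (42.1 and 64.9) and thapsigargin (59.2 and 107) lay apart from the others (-56.7 to -6.16), and on the second (19.8%) untreated replicate 1 lay at 137, against -80.2 to 42.6.

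**Figure D1:**
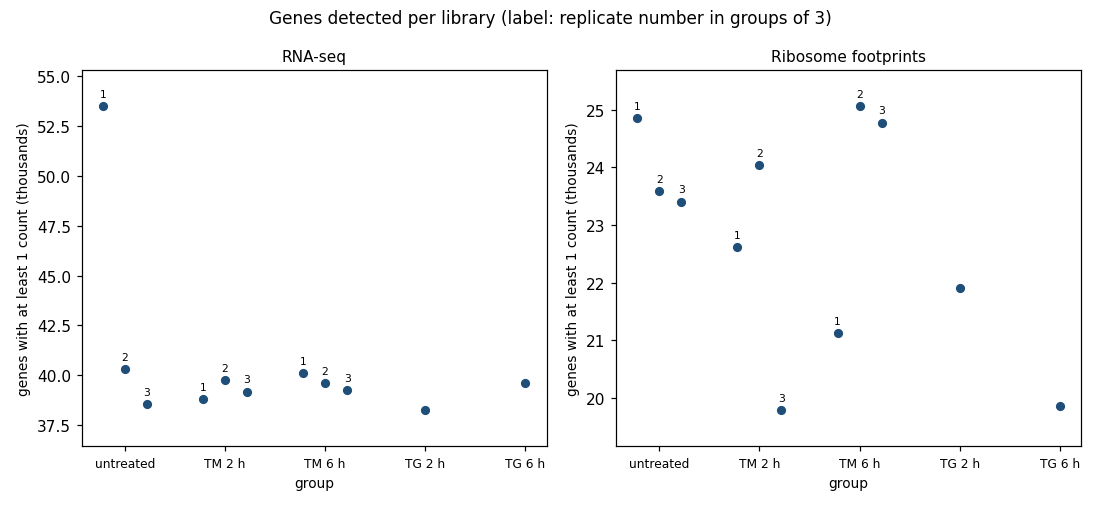
Number of genes with at least 1 count (vertical axis) in each group (horizontal axis) for RNA-Seq and Ribo-Seq, with 1 point per library and the replicate number beside it in groups of 3. RNA-Seq untreated replicate 1 had counts in 53489 genes.

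The 10 sentinel genes are all protein coding. Their RefSeq spans on GRCh38.p14 follow, with the chromosome in brackets. HSPA5 spans 125234853 to 125241343 (9), DNAJB9 108569874 to 108574850 (7) and HERPUD1 56932142 to 56944864 (16). XBP1 spans 28794560 to 28800569 (22), ATF4 39520559 to 39522686 (22), DDIT3 57516588 to 57520517 (12) and TRIB3 380760 to 397559 (20). ASNS spans 97851677 to 97928441 (7), MTHFD2 74198615 to 74217565 (2) and PSAT1 78297125 to 78330093 (9).

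The first comparison asked which transcripts differed in abundance after 6 h of tunicamycin (n = 3) from untreated cells (n = 3). HSPA5, which encodes the ER chaperone BiP, rose from 885 ± 335 to 11235 ± 3977 CPM, a log2 fold change of 3.67 ± 0.518 (SE, adjusted p = 0.00782). HERPUD1, a component of ER-associated degradation, rose from 40.6 ± 3.37 to 1041 ± 79.2 CPM (4.68 ± 0.254, adjusted p = 7.54e-05), and the ER co-chaperone gene DNAJB9 from 18.5 ± 2.27 to 357 ± 52.8 CPM (4.27 ± 0.245, 7.54e-05). The transcription factor genes XBP1 (2.45 ± 0.261, adjusted p = 0.00162), DDIT3 (4.85 ± 0.515, 0.00161) and ATF4 (1.63 ± 0.299, 0.0256) rose, and so did the pseudokinase gene TRIB3 (4.39 ± 0.359, 0.000854). Genes of amino acid and folate metabolism rose too, with ASNS at 2.45 ± 0.397 (adjusted p = 0.0154), MTHFD2 at 2.31 ± 0.408 (adjusted p = 0.0222) and PSAT1 at 1.99 ± 0.35 (adjusted p = 0.0218).

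Of 26 genes in ER chaperones and folding 16 rose (23 adjusted over the list alone), including DNAJC3 (2.57) and ERO1B (2.44), with a median of 1.59 (camera adjusted p = 1.96e-71 and, with an estimated correlation, 0.00563). In ER-associated degradation 11 of 23 rose (16 adjusted over the list alone, SEL1L 2.58, DERL3 2.05, median 0.93, adjusted p = 1.08e-33 and, with an estimated correlation, 0.0148). In ER translocation and vesicle traffic 10 of 35 rose (23 adjusted over the list alone, SEC11C 2.22, SEC23B 2.11, ARFGAP3 1.70, median 0.96, adjusted p = 1e-31 and, with an estimated correlation, 0.0404). In the N-glycosylation and hexosamine pathway 5 of 31 rose (14 adjusted over the list alone): GFPT1 (2.69 ± 0.276), the first enzyme of hexosamine synthesis, PGM3 (2.32), ALG2 (1.77) and, named after their values were seen, OSTC (1.44) and MAGT1 (1.43). Its median was 0.53 (adjusted p = 4.86e-15 and, with an estimated correlation, 0.166). Of 13 UPR sensors and transcription factors 3 rose (5 adjusted over the list alone), the sensor genes EIF2AK3 (2.27) and ERN1 (1.79) and XBP1, with a median of 0.58 (adjusted p = 1.65e-08 and, with an estimated correlation, 0.0301).

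In PERK-ATF4 targets 10 of 26 rose (20 adjusted over the list alone, SESN2 3.83, median 1.65, adjusted p = 1.63e-40 and, with an estimated correlation, 0.00563). In mRNAs with regulatory uORFs 6 of 14 rose (8 adjusted over the list alone, IBTK 1.79, median 1.23, adjusted p = 1.02e-16 and, with an estimated correlation, 0.0148). In amino acid synthesis and transport 11 of 24 rose (16 adjusted over the list alone, CTH 3.40, GOT1 2.65, GPT2 2.22, median 1.60, adjusted p = 2.16e-32 and, with an estimated correlation, 0.0148). Of 20 cytosolic tRNA synthetases 8 rose (13 adjusted over the list alone, GARS1 2.10, WARS1 1.83, AARS1 1.77, median 1.21, adjusted p = 2.53e-22 and, with an estimated correlation, 0.0564). In one-carbon and folate metabolism the 3 mitochondrial enzyme genes ALDH1L2 (3.10), MTHFD2 and SHMT2 (1.69) rose among 26 (4 adjusted over the list alone, median 0.10, adjusted p = 0.000143 and, with an estimated correlation, 0.197). That median was -0.18 with library size alone, and the list did not pass without RNA-Seq untreated replicate 1 (median -0.02, adjusted p = 0.0575). In autophagy WIPI1 (2.36) and ATG13 (1.12) rose among 17 (6 higher and 1 lower adjusted over the list alone, median 0.52, adjusted p = 1.74e-07 and, with an estimated correlation, 0.031).

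A further 3 lists were higher by camera with no called member: the proteasome (31 genes, median 0.42, adjusted p = 2.04e-06), translation factors with TOP mRNAs (17 genes, 0.32, 0.00238) and replication-dependent histones (18 genes, 0.54, 0.00112). None of the 3 held with an estimated correlation (adjusted p = 0.559, 0.501 and 0.602), and none had a member called when adjusted over the list alone. Without RNA-Seq untreated replicate 1, the library with the extra detected genes, their adjusted p was 0.128, 0.103 and 0.326 in the same order. The histones were also lost without tunicamycin 6 h replicate 1 (0.264). Library size alone gave 0.0505 for the translation factors with TOP mRNAs. The other lists did not pass. Ribosomal proteins had a median of 0.08 over 79 genes (adjusted p = 0.112), mitochondrially encoded mRNAs 0.06 (13 genes, 0.805), extracellular matrix -0.19 (22 genes, 0.953) and IRE1-dependent decay substrates -0.29 (10 genes, 0.114), with none called over all genes or over the list alone. Immediate early genes (28 genes, median -0.08, mean 0.06, adjusted p = 0.265) and p53 targets (16 genes, -0.06, 0.08, 0.286) had no called member either, and both tests pointed up. In 5 lists a single gene was called, named here after its value was seen: STARD4 (1.64) rose in cholesterol synthesis (24 genes, 2 adjusted over the list alone, median -0.18, mean -0.07, test up, adjusted p = 0.286). CDC6 (2.65) rose in cell cycle and DNA replication (28 genes, 1 adjusted over the list alone, median 0.11, adjusted p = 0.114) and GFAP (1.15) in glial cell markers (11 genes, 2 higher and 3 lower adjusted over the list alone, median -0.82, adjusted p = 0.879). HSPA8 (-1.86) fell in cytosolic heat shock (18 genes, 2 lower adjusted over the list alone, median -0.06, adjusted p = 0.854) and TNFRSF10A (-1.73) in ER stress apoptosis (18 genes, 2 higher and 1 lower adjusted over the list alone, median -0.02, mean -0.03, test up, adjusted p = 0.286). Blood cell markers had a median of -0.46 (10 genes, adjusted p = 0.286) and epithelial cell markers of -0.27 with the test pointing up (10 genes, adjusted p = 0.953, 2 lower adjusted over the list alone).

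The highest with a symbol outside these lists were SPRR2D (5.21 ± 0.46, adjusted p = 0.00106), CMKLR2 (5.07, 0.00782), the pseudogene KRT8P9 (5.05), KLHDC7B (4.91) and LINC01583 (4.80). The lowest with a symbol were TRIL (-3.62 ± 0.72, adjusted p = 0.0368), S1PR5 (-2.90, 0.0189) and C4orf54 (-2.79, 0.0344). In all, edgeR called 617 genes (504 higher, 113 lower); 7148 had an unadjusted p under 0.05, and 21.1% of genes did not overlap between the groups, where chance gives 10%. The median of all genes was -0.27 with TMM and -0.58 with library size alone, which called 298 higher and 118 lower. The replicate block called 1624 genes and DESeq2 2485. Chosen after seeing the data, the block without untreated replicate 1 called 7439 and replicates 2 and 3 alone 5590. Leaving out 1 library gave 963 without untreated replicate 1, 195 without untreated 2, 376 without untreated 3, and 287, 272 and 187 without tunicamycin 6 h replicates 1, 2 and 3.

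Of the 46 named genes called at 6 h, 29 stayed called whichever library was left out. Without tunicamycin replicate 1, TRIL, S1PR5, C4orf54, ATF4, MTHFD2, PSAT1, ERN1, GARS1, SHMT2, ATG13 and 3 genes with no symbol were not called (adjusted p 0.0501 to 0.179). Without replicate 2 the same held for TRIL, C4orf54, ATF4, MTHFD2, PSAT1, ERN1, SHMT2, ATG13 and 2 with no symbol (0.0504 to 0.177). Without replicate 3 it held for TRIL, S1PR5, C4orf54, ATF4, ASNS, MTHFD2, PSAT1, ERN1, GARS1, SHMT2, ATG13 and 2 with no symbol (0.0585 to 0.239). Without untreated replicate 2 it held for KRT8P9, KLHDC7B, S1PR5, C4orf54, ATF4, ASNS, MTHFD2, PSAT1, ERN1, GARS1, SHMT2, IBTK, ATG13 and 1 with no symbol (0.0541 to 0.107). Without untreated 3 it held for C4orf54, ATF4, ERN1, SHMT2 and ATG13 (0.051 to 0.0691), and without untreated 1 for ERN1 (0.0841) and 1 with no symbol (0.0534). MTHFD2 also had an adjusted p of 0.0503 in a fit of the compared groups alone.

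**Figure D2:**
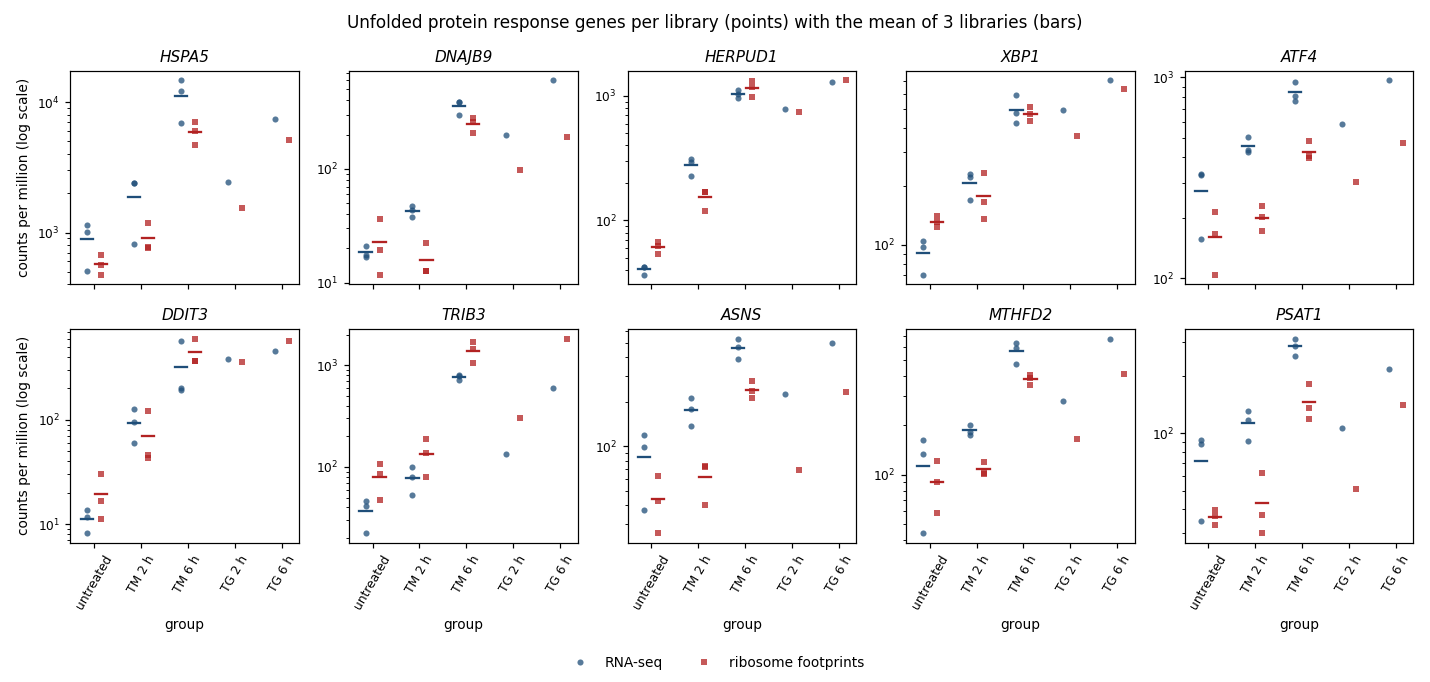
TMM-scaled CPM (vertical axis, log scale) of the 10 sentinel genes in each group (horizontal axis, TM, tunicamycin, TG, thapsigargin), with 1 point per RNA-Seq or Ribo-Seq library and a bar at the mean of groups of 3. HERPUD1 in RNA-Seq was at 40.6 CPM in untreated cells and at 1041 CPM after 6 h of tunicamycin.

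After 2 h of tunicamycin the question was which transcripts had moved first. HERPUD1 rose from 40.6 ± 3.37 to 278 ± 45.7 CPM (2.77 ± 0.233, adjusted p = 0.00355, n = 3 per group). The other 3 called genes were MIR616 (3.24, adjusted p = 0.00534), which lies within DDIT3, and ENSG00000261114 (3.51, 0.00355) and ENSG00000261270 (3.32, 0.00425), which have no symbol. DDIT3 was at 94.0 ± 33.1 against 11.2 ± 2.73 CPM (3.07 ± 0.474, adjusted p = 0.221) and CHAC1 at 58.5 ± 20.8 against 4.10 ± 2.68 CPM (3.84 ± 0.563, 0.203). HSPA5 (1.08), DNAJB9 (1.21), XBP1 (1.20), TRIB3 (1.08), ASNS (1.05), ATF4 (0.75), MTHFD2 (0.71) and PSAT1 (0.66) did not pass either.

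By camera 18 of the 27 lists were higher at 2 h, and 1 held with an estimated correlation: PERK-ATF4 targets (26 genes, 0 called, 5 adjusted over the list alone, median 0.68, adjusted p = 2.04e-20 and, with an estimated correlation, 0.0488). The other 17 had adjusted p of 0.0679 to 0.314 with an estimated correlation. They included immediate early genes (28 genes, 0 called, 5 adjusted over the list alone, median 1.10, adjusted p = 9.22e-20, EGR2 2.96, KLF10 1.97, DUSP6 1.04), with library medians of -0.45, 1.52 and 2.14 against the untreated mean, that of replicate 1 being the negative one. Medians of the others were 0.60 for cell cycle and DNA replication (CDC6 1.00, CDC25C 0.86), 0.55 for replication-dependent histones and 0.51 for mRNAs with regulatory uORFs (IFRD1 0.71, 2 adjusted over the list alone). They were 0.38 for amino acid synthesis and transport (CTH 1.38, SLC38A2 0.77, 1 adjusted over the list alone), 0.36 for cytosolic tRNA synthetases (CARS1 0.85), 0.35 for the proteasome, 0.32 for ER chaperones and folding (DNAJB11 1.07, 2 adjusted over the list alone) and 0.29 for p53 targets (MDM2 0.93, TIGAR 0.76). Medians were 0.27 for ER-associated degradation (HERPUD1 called, 1 adjusted over the list alone), 0.24 for cholesterol synthesis (IDI1 0.71, STARD4 0.68) and 0.23 for autophagy and for cytosolic heat shock (DNAJB1 0.90). They were 0.21 for ER translocation and vesicle traffic and for the N-glycosylation and hexosamine pathway and 0.19 for one-carbon and folate metabolism. UPR sensors and transcription factors had a median of 0.09 (EIF2AK3 0.84, 2 adjusted over the list alone), or -0.03 with library size alone. Without RNA-Seq untreated replicate 1 the test was lost for ER translocation and vesicle traffic (adjusted p = 0.349), N-glycosylation and hexosamine pathway (0.334), one-carbon and folate metabolism (0.57), autophagy (0.333), cytosolic heat shock (0.937, median -0.01), the proteasome (0.102) and p53 targets (0.055). Median and mean were negative while the test pointed up in ER stress apoptosis (-0.09, -0.10, 0.264) and extracellular matrix (-0.21, -0.19, 0.944), and neither passed. The edgeR test called 4 genes, all higher, and 3315 had an unadjusted p under 0.05; 7 were called without tunicamycin 2 h replicate 1, 68 by DESeq2 and 1269 with replicates 2 and 3 alone, a fit chosen after seeing the data. Between the groups 9.32% of genes did not overlap. Chance gives 10% only for interchangeable libraries without tied values, and genes with no counts in a library of each group could not qualify. The share is therefore not read against 10%. The median of all genes was -0.17 with TMM and -0.37 with library size alone.

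From 2 h to 6 h of tunicamycin (n = 3 per group), which asked what kept moving, ER chaperones and folding rose further: 12 of 26 genes (19 adjusted over the list alone, median 1.19, adjusted p = 3.33e-57 and, with an estimated correlation, 0.0198). PERK-ATF4 targets rose too, with 2 of 26 called (TRIB3 3.31 and GDF15 1.76, 14 adjusted over the list alone, median 1.02, adjusted p = 1.07e-17 and, with an estimated correlation, 0.0396). ER-associated degradation (6 of 23), ER translocation and vesicle traffic (5 of 35) and amino acid synthesis and transport (5 of 24) had calls too. Adjusted over the list alone they had 13, 21 and 13, and with an estimated correlation adjusted p = 0.0698, 0.131 and 0.0535. The calls in the last pair of lists, named after their values were seen, were SEC24D (2.32), SEC23B (1.66), USO1 (1.27), SEC31A (1.19) and GOSR2 (1.18), and CTH (2.02), GOT1 (1.90), GPT2 (1.69), CBS (1.67) and PYCR1 (1.31). Immediate early genes went the other way, with a median of -1.30, 0 called and 8 lower adjusted over the list alone (adjusted p = 1.37e-08 and, with an estimated correlation, 0.41). So did cell cycle and DNA replication (median -0.46, adjusted p = 5.57e-05 and, with an estimated correlation, 0.574), which was lost without tunicamycin 2 h replicate 1 (0.0609). Median, mean and test differed in sign for ER stress apoptosis, extracellular matrix and glial cell markers, which did not pass.

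With a symbol, the highest changes from 2 h to 6 h were those of CMKLR2 (5.31, adjusted p = 0.0128), KLHDC7B (5.20, 0.0137), HID1 (4.72, 0.00889) and SPRR2D (4.61, 0.00315). The lowest with a symbol were C4orf54 (-3.06, 0.0359) and SNED1-AS1 (-2.43, 0.0344). With no symbol, 1 gene lay above CMKLR2, 2 between C4orf54 and SNED1-AS1, and 1 next above the latter. The test called 305 genes (242 higher, 63 lower, 4009 with an unadjusted p under 0.05, 19.5% not overlapping), and 1121 with the replicate block. The block without untreated replicate 1 gave 10303 and replicates 2 and 3 alone 7230, both chosen after seeing the data. Without tunicamycin 2 h replicates 2 and 3 it called 37 and 23, and without 6 h replicates 1, 2 and 3 it called 159, 112 and 61. SPRR2D stayed called throughout. Without 2 h replicate 2, CMKLR2 (adjusted p = 0.101), KLHDC7B (0.0726), HID1 (0.0845), C4orf54 (0.159) and SNED1-AS1 (0.176) were not called, nor without 2 h replicate 3 (0.101, 0.111, 0.0918, 0.16 and 0.163). C4orf54 and SNED1-AS1 were also lost without 6 h replicate 1 (0.129, 0.128), 2 (0.121, 0.104) and 3 (0.202, 0.219), and KLHDC7B without 6 h replicate 2 (0.0503) and 3 (0.0722).

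Ribo-Seq asked the same of mRNAs under translation. After 6 h of tunicamycin, footprints on HSPA5 rose from 571 ± 101 to 5915 ± 1155 CPM (3.37 ± 0.378, adjusted p = 0.00143, n = 3 per group). They rose on HERPUD1 from 61.1 ± 6.55 to 1160 ± 164 CPM (4.25 ± 0.316, adjusted p = 0.000159) and on DDIT3 from 19.4 ± 9.92 to 441 ± 137 CPM (4.52 ± 0.528, 0.00238). TRIB3 (4.12 ± 0.441, adjusted p = 0.00114), DNAJB9 (3.46 ± 0.413, 0.00238), ASNS (2.46, 0.00718), MTHFD2 (2.08, 0.00666), PSAT1 (1.99, 0.00887) and XBP1 (1.85, 0.00806) rose, and ATF4 did not pass (1.41 ± 0.3, 0.0534). Among the highest were also SESN2 (3.54), LINC01583 (3.58), AKNA (3.44) and FICD (3.40), an enzyme that modifies BiP. The lowest were DLX5 (-3.44, adjusted p = 0.0274), DGAT2 (-3.33, 0.00114), S1PR5 (-3.15), PPARGC1B (-2.80), GAS1 (-2.42) and VANGL2 (-2.22).

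Of 26 ER chaperone and folding genes 11 rose in footprints (17 adjusted over the list alone, SDF2L1 2.68, median 1.30, adjusted p = 3.54e-37 and, with an estimated correlation, 0.00665). In ER-associated degradation 6 of 23 rose (11 adjusted over the list alone, SYVN1 2.38, SEL1L 1.94, adjusted p = 6.43e-15 and, with an estimated correlation, 0.00904). In amino acid synthesis and transport 10 of 23 rose (17 adjusted over the list alone, GOT1 2.47, adjusted p = 1.55e-24 and, with an estimated correlation, 0.00469). Of cytosolic tRNA synthetases 6 of 20 rose (12 adjusted over the list alone, GARS1 1.96, AARS1 1.81, WARS1 1.58, adjusted p = 1.95e-17 and, with an estimated correlation, 0.0115). Among 25 PERK-ATF4 targets DDIT3, TRIB3, SESN2, GDF15 (2.52) and, named after its value was seen, CEBPG (1.87) rose (16 adjusted over the list alone, adjusted p = 3.12e-29 and, with an estimated correlation, 0.00665). Among 14 mRNAs with regulatory uORFs DDIT3 and SESN2 rose (7 adjusted over the list alone, adjusted p = 3.7e-09 and, with an estimated correlation, 0.00665). Further lists passed by camera and were lost with an estimated correlation. In ER translocation and vesicle traffic SEC24D (2.37), SEC23B (2.01) and ARFGAP3 (1.44) rose among 35 (11 adjusted over the list alone, adjusted p = 4.44e-11 and, with an estimated correlation, 0.0941). In the N-glycosylation and hexosamine pathway GFPT1 (2.54), PGM3 (1.91) and UAP1 (1.86) rose among 31 (5 adjusted over the list alone, adjusted p = 0.000505 and, with an estimated correlation, 0.0941). In one-carbon and folate metabolism ALDH1L2 (2.84), MTHFD2 and SHMT2 (1.50) rose among 25 (3 adjusted over the list alone, adjusted p = 0.0081 and, with an estimated correlation, 0.118). EIF2AK3 (1.59) and XBP1 rose among 13 UPR sensors and transcription factors (2 adjusted over the list alone, adjusted p = 0.00908 and, with an estimated correlation, 0.156). WIPI1 (1.97) rose among 17 autophagy genes (1 adjusted over the list alone, adjusted p = 0.0081 and, with an estimated correlation, 0.0788). The 9 tested IRE1-dependent decay substrates, mRNAs that the IRE1 nuclease is reported to cleave, were lower as a list (median -0.76, 0 called, 3 lower adjusted over the list alone, adjusted p = 0.000114 and, with an estimated correlation, 0.0941, PMP22 -1.02, TGOLN2 -1.01, CD59 -0.94). The proteasome (median 0.43, adjusted p = 0.000215 and, with an estimated correlation, 0.486) and replication-dependent histones (0.54, adjusted p = 0.00321 and, with an estimated correlation, 0.646) were higher with 0 members called by either adjustment. STARD4 (1.41) and CDC6 (2.40) rose and HSPA8 (-1.52) fell in lists that did not pass, named after their values were seen. Ribosomal proteins (median -0.02) and cell cycle and DNA replication (-0.01, mean 0.07) did not pass, and both tests pointed up.

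In Ribo-Seq at 6 h, edgeR called 163 genes (130 higher, 33 lower, 2342 with an unadjusted p under 0.05, 20.6% not overlapping), 386 with the replicate block and 686 with DESeq2. The later fits named above called 651 and 378. Without untreated replicates 2 and 3 it called 34 and 37, and without tunicamycin replicates 1, 2 and 3 it called 80, 48 and 44. Of the 37 named genes called, 15 stayed called throughout. Without untreated replicate 2, 22 were not called, among them XBP1 (adjusted p = 0.0581), ASNS (0.0565), MTHFD2 (0.0541), PSAT1 (0.0671), SEL1L (0.0578), SEC23B (0.0541), GARS1 (0.0613) and WIPI1 (0.0503). Without untreated replicate 3, 16 were not called (0.0506 to 0.124), with XBP1 at 0.0663 and PSAT1 at 0.0579. Without tunicamycin replicate 3, 15 were not called (0.0559 to 0.162), with XBP1 at 0.0559, and without replicates 2 and 1 it was 13 (0.0507 to 0.214) and 8 (0.0743 to 0.186). LINC01583, DLX5, S1PR5, PPARGC1B, VANGL2, ARFGAP3, UAP1 and SHMT2 were among those lost in each of these fits, SESN2, SYVN1, EIF2AK3, AARS1 and WARS1 in all but the last, and PGM3 in those without untreated 2 (0.078), untreated 3 (0.0658) and tunicamycin 3 (0.0559). Without untreated replicate 1, SESN2, S1PR5, PPARGC1B and VANGL2 were not called (0.0647 to 0.0884). Of the lists, UPR sensors and transcription factors was lost without untreated replicate 2 (0.0537) and 3 (0.066), one-carbon and folate metabolism without untreated 2 (0.0867) and tunicamycin 1 (0.0703). The proteasome was lost without tunicamycin 1 (0.0799), and replication-dependent histones without untreated 1 (0.214) and tunicamycin 1 (0.479).

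After 2 h of tunicamycin no footprint change passed. HERPUD1 was at 153 ± 29.8 against 61.1 ± 6.55 CPM (1.32 ± 0.282), DDIT3 at 69.9 ± 44.0 against 19.4 ± 9.92 CPM (1.86 ± 0.475), CHAC1 at 2.60 ± 0.845 and DNAJB9 at -0.51 (adjusted p = 1 for each, n = 3 per group). The sign for DNAJB9 rested on untreated replicate 1, at 36.6 CPM against 19.4 and 11.8 CPM in the others. Without it the value was 0.0460, and fits chosen after seeing the data gave 0.19 (with the block besides) and 0.21 (replicates 2 and 3 alone). By camera 8 lists were higher and none held with an estimated correlation (adjusted p = 0.515 to 0.79). They were immediate early genes (median 0.72, EGR2 1.67, EGR3 1.66, adjusted p = 1.85e-07), cell cycle and DNA replication (0.39, adjusted p = 1.85e-07), replication-dependent histones (0.43, H1-2 0.83) and mitochondrially encoded mRNAs (0.37, MT-CO1 1.24). The others were p53 targets (0.35), PERK-ATF4 targets (0.35, adjusted p = 1.1e-05), the proteasome (0.26) and mRNAs with regulatory uORFs (0.16, 1 adjusted over the list alone, 0 in the other 7). Immediate early genes had a median of -0.18 without tunicamycin 2 h replicate 3 (adjusted p = 0.863). Without that replicate mRNAs with regulatory uORFs (0.183) and p53 targets (0.174) were lost, and without tunicamycin replicate 1 the proteasome (0.604), mitochondrially encoded mRNAs (0.951) and replication-dependent histones (0.0925). Without untreated replicate 1 mRNAs with regulatory uORFs (0.103), the proteasome (0.08), mitochondrially encoded mRNAs (0.764) and replication-dependent histones (0.0639) were lost. Without untreated 2 it was mRNAs with regulatory uORFs (0.0563) and p53 targets (0.0569), without untreated 3 mRNAs with regulatory uORFs (0.123), and without tunicamycin 2 mitochondrially encoded mRNAs (0.112). The edgeR test called 0 genes, with 619 at an unadjusted p under 0.05, and DESeq2 called 3; 6.33% of genes did not overlap, where chance gives 10%. Median and mean or test differed in sign for ER-associated degradation, autophagy and glial cell markers, which did not pass.

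Between 2 h and 6 h, footprints on DNAJB9 (3.97, adjusted p = 0.00136), CTH (3.79, 0.00521), BEX2 (3.74, 0.0148), LINC01583 (3.50, 0.0418) and ALDH1L2 (3.47, 0.000606) rose most. DGAT2 (-2.89, 0.00298), GAS1 (-2.17, 0.00546), PTCH1 (-2.16, 0.0208), E2F2 (-1.95, 0.00724) and B3GNT7 (-1.93, 0.0177) fell most. Of 14 lists that passed, 7 held with an estimated correlation. In ER chaperones and folding 11 of 26 rose, in ER-associated degradation 7 of 23, and in amino acid synthesis and transport 6 of 23. Adjusted over the list alone these were 16, 11 and 12, with adjusted p = 0.0131, 0.0131 and 0.0118 with an estimated correlation. The calls of the other 4 lists are named after their values were seen. SEC24D (2.63), SEC23B (1.96) and ARFGAP3 (1.58) rose among 35 genes of ER translocation and vesicle traffic (16 adjusted over the list alone, adjusted p = 0.0417 with an estimated correlation). TRIB3 (3.38), DDIT3 (2.65), GDF15 (1.87) and CEBPG (1.63) rose among 25 PERK-ATF4 targets (13 adjusted over the list alone, adjusted p = 0.0192 with an estimated correlation). GARS1 (1.80), WARS1 (1.58) and AARS1 (1.42) rose among 20 cytosolic tRNA synthetases (12 adjusted over the list alone, adjusted p = 0.0179 with an estimated correlation). DDIT3 was the 1 call among 14 mRNAs with regulatory uORFs (7 adjusted over the list alone, adjusted p = 0.0131 with an estimated correlation). IRE1-dependent decay substrates were lower (median -0.65, adjusted p = 0.000448 and, with an estimated correlation, 0.122). The test called 146 genes (118 higher, 28 lower, 1950 with an unadjusted p under 0.05, 17.6% not overlapping), and 364 with the replicate block. The same later fits called 1614 and 639. Without tunicamycin 2 h replicates 2 and 3 it called 30 and 61, and without 6 h replicates 1, 2 and 3 it called 70, 32 and 31. DNAJB9, ALDH1L2 and DGAT2 stayed called throughout. LINC01583 was lost in every fit that left out 1 of the 6 libraries (adjusted p 0.104 to 0.194). PTCH1 was lost without 2 h replicates 2 and 3 (0.0636, 0.0812) and 6 h replicates 1, 2 and 3 (0.0555, 0.125, 0.116), and BEX2 without 2 h replicate 2 (0.088) and 6 h replicates 1 to 3 (0.0501, 0.0541, 0.0916). B3GNT7 was lost without 6 h replicates 1 to 3 (0.0541, 0.123, 0.116), E2F2 without 6 h replicates 2 and 3 (0.0653, 0.0803), GAS1 without 6 h replicate 2 (0.0587) and CTH without 2 h replicate 2 (0.0551). Median and mean or test differed in sign for mitochondrially encoded mRNAs and replication-dependent histones, which did not pass.

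**Figure D3:**
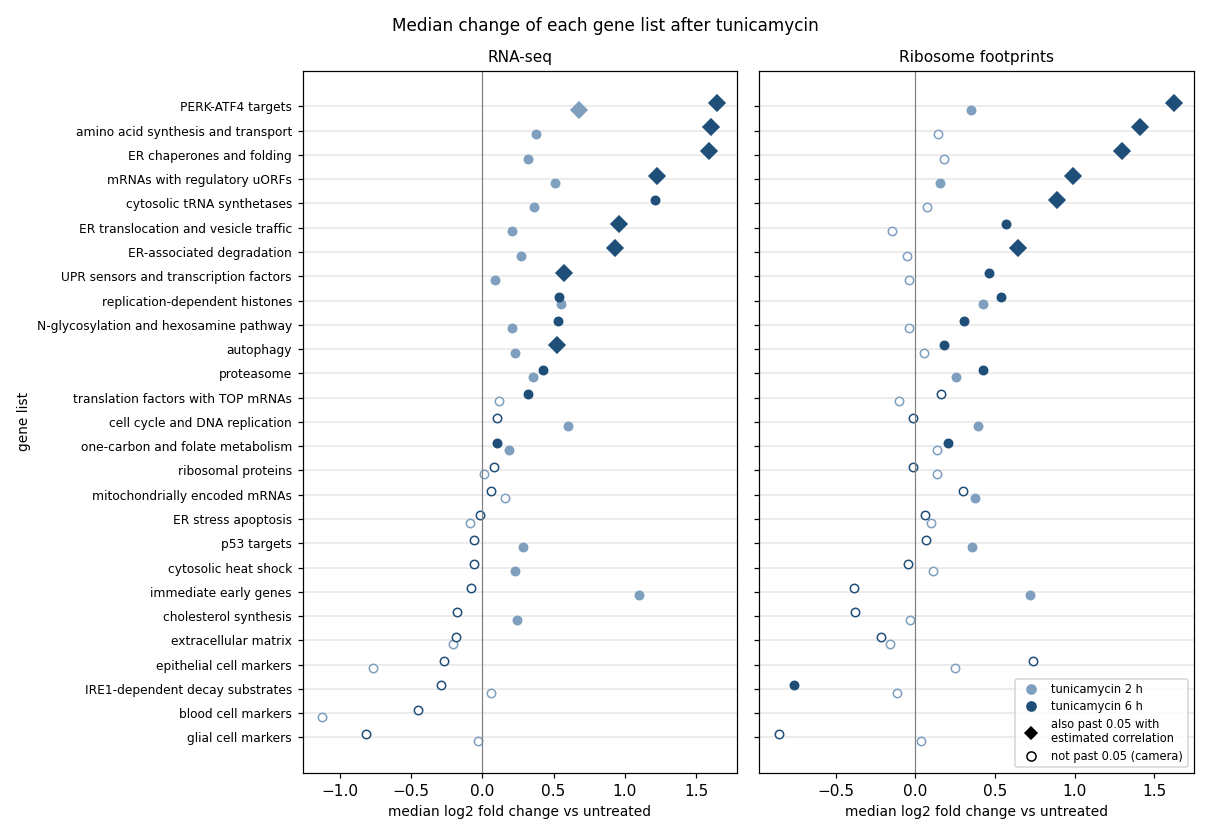
Median log2 fold change (horizontal axis) of each gene list (vertical axis) after 2 h (light) and 6 h (dark) of tunicamycin against untreated cells, in RNA-Seq and in Ribo-Seq, with 1 point per list and time. Open points did not pass camera and diamonds also passed with an estimated correlation. ER chaperones and folding had a median of 1.59 in RNA-Seq and 1.30 in Ribo-Seq at 6 h.

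The next question was whether footprints changed beyond RNA. After 6 h of tunicamycin, 476 RNA-Seq and 163 Ribo-Seq calls lay among the 18500 genes tested in both assays; 119 genes were higher and 14 lower in both, where independent lists would share 4.19 in total. Among these 133 genes the median log2 change, taken with its sign, was 2.08 in RNA and 1.84 in footprints. The size of the change was smaller in footprints for 105. Across genes, which are not independent replicates, the 2 sets of changes had r = 0.253 (Spearman's rho 0.505). For translational efficiency at 2 h and 6 h edgeR called 0 genes at each time, with 726 and 686 at an unadjusted p under 0.05. The alternatives differed: DESeq2 called 14 and 20, limma voom 0 and 0, and separate fits 2 and 0. The sentinel genes lay between -0.64 and 0.10 at 6 h, and at 2 h DNAJB9 was at -1.58 ± 0.466, HERPUD1 at -1.35 ± 0.315 and DDIT3 at -1.07 ± 0.679 (adjusted p = 1 for each).

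By list, efficiency was lower after 6 h in ER translocation and vesicle traffic (median -0.29, adjusted p = 0.000903), ER chaperones and folding (-0.24, 0.0392), ER-associated degradation (-0.23, 0.0392), N-glycosylation and hexosamine pathway (-0.13, 0.0392) and UPR sensors and transcription factors (-0.35, 0.0492), with 0 members called by either adjustment (adjusted p = 0.654 for each with an estimated correlation). The replicate block gave 0.0759 for ER chaperones and folding, and DESeq2's size factors (0.0604 for each) and library size alone (0.0636) ended all but the first. All 5 were lost without RNA-Seq untreated replicate 1 (0.085 to 0.357). Of them 4 were lost without RNA-Seq untreated 2 (0.0714 to 0.117), tunicamycin 3 (0.156 to 0.175), Ribo-Seq untreated 1 (0.0523 to 0.256) and 3 (0.15 to 0.293), and tunicamycin 1 (0.259) and 2 (0.105 to 0.145). UPR sensors and transcription factors was also lost without RNA-Seq untreated 3 (0.0566), RNA-Seq tunicamycin 2 (0.0546) and Ribo-Seq untreated 2 (0.0607), the last also ending ER-associated degradation (0.0696). After 2 h it was lower in ER translocation and vesicle traffic (-0.26, 0.00774), ER-associated degradation (-0.16, 0.0406, 1 lower adjusted over the list alone), cholesterol synthesis (-0.23, 0.0406), mRNAs with regulatory uORFs (-0.39, 0.0406) and PERK-ATF4 targets (-0.28, 0.0447). It was higher in ribosomal proteins (0.28, 0.017), with adjusted p = 0.658 for the first 5 and 0.919 for the last with an estimated correlation. All 6 were lost without RNA-Seq untreated 1 (0.273 to 0.508), RNA-Seq tunicamycin 3 (0.0618 to 0.568) and Ribo-Seq untreated 3 (0.0522 to 0.298). From 4 to 5 of them were lost without RNA-Seq tunicamycin 2 (0.0516 to 0.263) or Ribo-Seq untreated 2 (0.0918 to 0.313), tunicamycin 1 (0.118 to 0.707) or tunicamycin 2 (0.174 to 0.197). RNA-Seq untreated 2 ended ER-associated degradation (0.0501) and cholesterol synthesis (0.0571), Ribo-Seq untreated 1 cholesterol synthesis (0.0947) and Ribo-Seq tunicamycin 3 ER translocation and vesicle traffic (0.129). Without Ribo-Seq tunicamycin 1 the median of ribosomal proteins was -0.10, and without RNA-Seq tunicamycin 3 that of cholesterol synthesis was 0.01.

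Thapsigargin was examined to see how a second ER stressor acted; each time had 1 library with no replicate check, and in RNA-Seq both libraries shared the low mitochondrial share and second component of the tunicamycin replicate 1 libraries. After 2 h, RNA of DDIT3 (380 CPM, 5.08, adjusted p = 0.013), the immediate early gene NR4A2 (676 against 25.8 ± 9.75 CPM, 4.71, 0.0343) and CHAC1 (4.42, 0.0416) rose, as did HERPUD1 (788 CPM, 4.28, 0.000627), DNAJB9 (199 CPM, 3.43, 0.00153) and XBP1 (492 CPM, 2.44, 0.0243). HSPA5 (1.48), TRIB3 (1.87), ASNS (1.42), MTHFD2 (1.31), ATF4 (1.10) and PSAT1 (0.56) did not pass. After 6 h, DNAJB9 (598 CPM, 5.02, adjusted p = 7.27e-05), HERPUD1 (1306 CPM, 5.01, 7.27e-05), DDIT3 (461 CPM, 5.36, 0.00256), TRIB3 (4.04, 0.00199) and HSPA5 (7489 CPM, 3.08, 0.033) rose. XBP1 (2.95, adjusted p = 0.00256), MTHFD2 (2.57, 0.0334), ASNS (2.55, 0.0302) and ATF4 (1.83, 0.0424) rose, and PSAT1 did not pass (1.60, 0.103). The cytokine gene IL6 rose from 0.814 ± 0.568 to 42.7 CPM (5.73, adjusted p = 0.0141), with SYT4 (5.44) and CMKLR2 (5.42), while WNK4 (-4.42), AATK (-4.33), TMEM121 (-4.26) and APLN (-4.25, 0.0129) fell.

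At 6 h of thapsigargin 16 of 26 ER chaperone and folding genes rose in RNA (23 adjusted over the list alone, median 1.85, adjusted p = 2.42e-48 and, with an estimated correlation, 0.0146). In ER-associated degradation 11 of 23 rose (16 adjusted over the list alone, adjusted p = 0.0293 with an estimated correlation). Of PERK-ATF4 targets 9 of 26 rose (17 adjusted over the list alone, adjusted p = 0.0146 with an estimated correlation), and in amino acid synthesis and transport 9 of 24 (11 adjusted over the list alone, adjusted p = 0.0476 with an estimated correlation). Another 3 lists held: 6 of 14 mRNAs with regulatory uORFs rose (9 adjusted over the list alone, adjusted p = 0.0293 with an estimated correlation), XBP1 and EIF2AK3 (2.96) rose among 13 UPR sensors and transcription factors (5 adjusted over the list alone, adjusted p = 0.0429 with an estimated correlation), and WIPI1 (2.94), GABARAPL1 (2.31) and ATG13 (1.31) rose among 17 autophagy genes (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0429 with an estimated correlation). EIF2AK3, WIPI1, GABARAPL1 and ATG13 were named here after their values were seen. Mitochondrially encoded mRNAs were lower (median -1.43, 0 called by either adjustment, adjusted p = 0.0108 and, with an estimated correlation, 0.648), beside the low mitochondrial share of these libraries. Blood cell markers (-2.10, adjusted p = 0.0331, 0 called by either adjustment) and glial cell markers (-1.66, adjusted p = 0.0443, 1 lower adjusted over the list alone) were lower, beside the extra detected genes of untreated replicate 1, with adjusted p = 0.146 and 0.158 with an estimated correlation. At 2 h immediate early genes had a median of 1.33 (1 of 28 called, NR4A2, 10 adjusted over the list alone, adjusted p = 7.63e-13 and, with an estimated correlation, 0.253). Median and mean differed in sign, with the test up and not passing, for one-carbon and folate metabolism at both times (2 h 0.20 and -0.23, 6 h 0.02 and -0.07), for ER stress apoptosis at both times and for p53 targets at 6 h. Cell cycle and DNA replication at 6 h had a negative median and mean with the test up. The test called 41 genes at 2 h (40 higher, 1 lower, 4338 with an unadjusted p under 0.05) and 737 at 6 h (613 higher, 124 lower, 6984), or 292 higher and 122 lower at 6 h with library size alone. The median of all genes was -0.38 and -0.50, or -0.71 and -0.86 with library size alone. A fit of the compared groups alone called 0 at each time, and DESeq2 called 770 and 3528. Leaving out untreated replicates 1, 2 and 3 gave 107, 7 and 11 genes at 2 h and 2411, 178 and 262 at 6 h. At 2 h DDIT3, NR4A2, CHAC1 and XBP1 were lost without untreated 2 (0.0635, 0.182, 0.0985, 0.122) and 3 (0.0508, 0.131, 0.131, 0.0883). At 6 h HSPA5 (0.0879), ATF4 (0.0808), ASNS (0.0781), MTHFD2 (0.0811), IL6 (0.0578), WNK4 (0.0813), AATK (0.0807) and TMEM121 (0.0576) were lost without untreated 2, and HSPA5 (0.0647), ATF4 (0.0731), WNK4 (0.0682) and AATK (0.0612) without untreated 3.

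In footprints, whose thapsigargin libraries lay with tunicamycin replicate 1 on the first component, 2 h of thapsigargin raised NR4A2 (966 against 32.9 ± 10.4 CPM, 4.87, adjusted p = 0.00393), DDIT3 (4.20, 0.0228), HERPUD1 (3.59, 0.00393) and RGS2 (3.86, 0.00393), an inhibitor of G protein signalling. The pseudogenes RN7SKP226 (6.21) and RN7SKP71 (6.06) were higher and the small RNAs SCARNA10 (-4.86), SNORD71 (-4.79), SNORA77 (-4.40), RNU6-761P (-3.47) and SCARNA6 (-3.24) lower; such RNAs are not translated. After 6 h, DDIT3 (4.90, adjusted p = 0.00311), TRIB3 (4.52, 0.00245), HERPUD1 (4.45, 0.000422), HSPA5 (3.18, 0.00617), DNAJB9 (3.07, 0.0129), ASNS (2.41, 0.0218), XBP1 (2.27, 0.0111), MTHFD2 (2.18, 0.0164) and PSAT1 (1.94, 0.031) rose, and ATF4 did not pass (1.55, 0.0864). MANEA (-5.22, 0.0256), CYP2U1 (-4.79), CNR1 (-4.77) and SNORD126 (-4.40) fell; PCDHB14 also passed (adjusted p = 0.00527), from 17.7 CPM in untreated cells to a level below the floor of 3 counts in the treated library, and no fold is given. The 5 highest were 5S ribosomal RNA pseudogenes (RNA5SP512 9.92, RNA5SP88 8.99, RNA5SP494 8.95, RNA5SP229 8.68, RNA5SP516 8.46), near-identical copies whose values are uncertain. Of the lists, 7 held at 6 h with an estimated correlation. In ER chaperones and folding 7 of 26 rose (12 adjusted over the list alone, adjusted p = 0.0337 with an estimated correlation), and in amino acid synthesis and transport 6 of 23 (10 adjusted over the list alone, adjusted p = 0.0155 with an estimated correlation). Of cytosolic tRNA synthetases 6 of 20 rose (10 adjusted over the list alone, adjusted p = 0.0351 with an estimated correlation). The calls of the other 4 lists are named after their values were seen. SESN2 (4.33), DDIT4 (3.20), GDF15 (3.07), DDIT3 and TRIB3 rose among 25 PERK-ATF4 targets (14 adjusted over the list alone, adjusted p = 0.0155 with an estimated correlation). DERL3 (4.17), SYVN1 (2.84), SELENOK (2.03) and HERPUD1 rose among 23 genes of ER-associated degradation (10 higher and 1 lower adjusted over the list alone, adjusted p = 0.0351 with an estimated correlation). IFRD1 (1.80), DDIT3 and SESN2 rose among 14 mRNAs with regulatory uORFs (6 adjusted over the list alone, adjusted p = 0.0122 with an estimated correlation). WIPI1 (2.84) rose among 17 autophagy genes (5 adjusted over the list alone, adjusted p = 0.0484 with an estimated correlation). At 2 h only mRNAs with regulatory uORFs held among the lists (1 of 14, DDIT3, 3 adjusted over the list alone, adjusted p = 4.23e-07 and, with an estimated correlation, 0.0299). Median, mean or test differed in sign at both times for one-carbon and folate metabolism, ER stress apoptosis and epithelial cell markers. The same held at 2 h for ER-associated degradation, UPR sensors and transcription factors and autophagy, and at 6 h for cytosolic heat shock, cell cycle and DNA replication and p53 targets, none of which passed.

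The Ribo-Seq test called 16 genes at 2 h of thapsigargin (11 higher, 5 lower, 1062 with an unadjusted p under 0.05) and 189 at 6 h (145 higher, 44 lower, 2759); the median of all genes was -0.15 and -0.27. A fit of the compared groups alone called 0 at each time. Without untreated replicates 1, 2 and 3 it called 26, 9 and 3 at 2 h and 300, 66 and 63 at 6 h. At 2 h DDIT3 was lost without untreated 1 (adjusted p = 0.0654) and 3 (0.135), RN7SKP226 without each (0.105, 0.128, 0.131), RN7SKP71 without 2 and 3 (0.0626, 0.0747), and RNU6-761P without 2 and 3 (0.12, 0.135). Without 3 the same held for SCARNA10, SNORA77 and SCARNA6 (0.0747 for each) and SNORD71 (0.0792). At 6 h ASNS (0.0727), MTHFD2 (0.0611), DNAJB9 (0.055) and PSAT1 (0.099) were lost without untreated 2 and XBP1 (0.0553), PSAT1 (0.096) and SNORD126 (0.0625) without untreated 3. Either loss ended CYP2U1 (0.0528, 0.0528), CNR1 (0.0611, 0.0648), RNA5SP512 (0.0774, 0.0805), RNA5SP494 (0.0539, 0.12) and RNA5SP516 (0.0924, 0.137). Translational efficiency under thapsigargin had 1 called gene at 2 h, the small nucleolar RNA gene SNORD71 (-5.82, adjusted p = 0.00277, 797 genes with an unadjusted p under 0.05). It was lost with limma voom (0.166), which called 1 other gene, and with the compared groups alone (0.800, 0 calls). DESeq2 called 58, separate fits 13, and fits without 1 library 1 to 3. At 6 h edgeR called 0 (1923 with an unadjusted p under 0.05, DESeq2 119, limma voom 1, separate fits 26, and 1 without Ribo-Seq untreated 2). By list, ER-associated degradation was lower at both times (-0.49 and -0.56, adjusted p = 0.00363 and 0.0277, adjusted p = 0.729 and 0.97 with an estimated correlation).

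Set against tunicamycin at the same time, thapsigargin had higher RNA of RGS16 at 2 h (64.8 against 8.96 ± 0.931 CPM, 2.85, adjusted p = 0.0368), and of HSPA8P16 (3.64), RPS10P14 (3.37), MIR921 (3.15) and a Y_RNA copy (3.11), whose values are uncertain. In footprints NR4A2 (966 against 44.5 ± 27.4 CPM, 4.45, adjusted p = 0.0148), RGS2 (168 against 13.3 ± 4.16 CPM, 3.65, 0.0148), DMRTA1 (2.83, 0.0363) and RNA5SP183 (7.07, 0.0363) were higher and SCARNA6 (-3.28, 0.0363) lower at 2 h. At 6 h RGS2 (62.1 against 5.93 ± 1.03 CPM, 3.38, adjusted p = 0.0284), MAP1A (2.74, 0.0361) and RNA5SP229 (8.63, 0.0205) were higher. RNA5SP88 also passed at 6 h (adjusted p = 0.0361); its tunicamycin libraries were all at 0 and no fold is given. RNA-Seq had 11 calls at 2 h, all higher, and 0 at 6 h (2341 with an unadjusted p under 0.05, DESeq2 375), and Ribo-Seq had 5 and 4. At 2 h DESeq2's size factors, library size alone, a minimum count of 50, the compared groups alone and the later-chosen filter on the 3-library groups each called 0 genes in RNA-Seq (DESeq2 250). Every RNA-Seq call was lost without any 1 of the tunicamycin 2 h libraries (RGS16 and the other named genes at adjusted p 0.186 to 0.316). In Ribo-Seq at 2 h, NR4A2 was lost without tunicamycin replicate 1 (0.0945) and 2 (0.0781), and RGS2 without 1 (0.0552), 2 (0.07) and 3 (0.0681); DMRTA1, SCARNA6 and RNA5SP183 were also lost without each (0.0681 to 0.165). At 6 h RGS2 was lost without replicate 1 (0.168), 2 (0.194 to 0.208 for all 4 genes) and 3 (0.161 to 0.165 for all 4), and RNA5SP88 (0.168) and MAP1A (0.17) without replicate 1. No list held with an estimated correlation. In RNA cholesterol synthesis was higher at 6 h (median 0.43, 0 called, 6 adjusted over the list alone, adjusted p = 1.75e-06 and, with an estimated correlation, 0.571). Mitochondrially encoded mRNAs were lower at 2 h and 6 h (-1.18 and -1.51, adjusted p = 0.00197 and 0.00042, adjusted p = 0.823 and 0.883 with an estimated correlation), beside the low mitochondrial share of the thapsigargin libraries.

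The changes under the 2 drugs were correlated across genes, which are not independent replicates, and both used the same 3 untreated libraries. In RNA-Seq r was 0.805 at 2 h and 0.817 at 6 h, where 12 simulated sets of unchanged groups sharing 3 simulated controls gave 0.328 and 0.342. In Ribo-Seq it was 0.385 and 0.424, where they gave 0.298 and 0.292. The covariances were 3.22, 3.27, 0.903 and 1.35, against simulated 0.445, 0.450, 0.442 and 0.448. With the untreated libraries kept as observed in the simulation, chosen after seeing the data, r was 0.818, 0.826, 0.481 and 0.473, the covariances were 3.62, 3.59, 0.852 and 0.865, and the differences -0.396, -0.316, 0.0511 and 0.481. Simulated covariances that high mean that the simulated groups lay off the mean of the 3 observed controls. This comparison therefore cannot decide whether the drugs share changes. In Ribo-Seq at 2 h the difference lay beside a simulated SD of 0.0261. Without untreated replicate 1 the RNA-Seq r was 0.567 at 2 h and 0.699 at 6 h, where 12 simulated sets with 2 shared controls, chosen after seeing the data, gave 0.420 and 0.433. The covariances were then 0.400 and 0.744 against simulated 0.160 and 0.161, a difference of 0.240 and 0.582. In Ribo-Seq without that replicate r was 0.323 and 0.377 against simulated 0.406 and 0.393, and the covariances differed by 0.0402 and 0.460. These simulations drew the controls anew. At 6 h 341 genes were called higher under both drugs in RNA (of 613 and 504) and 27 lower (of 124 and 113). In footprints it was 83 higher (of 145 and 130) and 7 lower (of 44 and 33). The simulated groups shared 0 at 6 h with either set of 3 controls, but hold no batch common to both drugs.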

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

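The results in this part differed between 2 h and 6 h of tunicamycin by a test of the 6 h libraries against the 2 h libraries, with effects against untreated cells that pointed opposite ways. The test of each tunicamycin library was chosen after the result was seen, and the test without untreated replicate 1 was set before.

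In RNA-Seq the fitted effects of 163 of the 305 genes called between 2 h and 6 h had opposite signs, 55 positive at 2 h and negative at 6 h and 108 the reverse. The genes were taken for their difference, which favours opposite signs, and no chance share was computed. The 2 h comparison called 4 genes, all higher at both times, so none of the 163 effects at 2 h passed. By list, the median change from 2 h to 6 h was -1.30 for immediate early genes (1.10 at 2 h and -0.08 at 6 h against untreated cells, camera adjusted p = 1.37e-08), -0.32 for cholesterol synthesis (0.24 and -0.18, 0.0222), -0.39 for IRE1-dependent decay substrates (0.06 and -0.29, 0.00401) and -0.36 for cytosolic heat shock (0.23 and -0.06, 0.00185). None of the 4 held, at adjusted p = 0.41, 0.574, 0.345 and 0.505 with an estimated correlation. Cholesterol synthesis was lost without tunicamycin 2 h replicate 3 (0.368), and cytosolic heat shock with replicates 2 and 3 alone (0.113).

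In Ribo-Seq 89 of the 146 called genes had fitted effects of opposite sign, 20 positive at 2 h and negative at 6 h and 69 the reverse. They were taken in the same way, and none passed at 2 h, where edgeR called 0 genes and DESeq2 3. The median change from 2 h to 6 h was 0.63 for ER-associated degradation (-0.05 at 2 h and 0.64 at 6 h against untreated cells, adjusted p = 7.07e-15) and 0.80 for ER translocation and vesicle traffic (-0.14 and 0.57, 1.64e-16), and these held at 0.0131 and 0.0417 with an estimated correlation. It was 0.33 for the N-glycosylation and hexosamine pathway (-0.04 and 0.31, 9.88e-05), 0.73 for UPR sensors and transcription factors (-0.04 and 0.46, 0.00304), -1.15 for immediate early genes (0.72 and -0.38, 1.46e-05) and -0.36 for cell cycle and DNA replication (0.39 and -0.01, 0.00531). These did not hold, at adjusted p = 0.0593, 0.12, 0.475 and 0.665 with an estimated correlation. Immediate early genes were lost without tunicamycin 2 h replicate 3 (0.229), and cell cycle and DNA replication without 2 h replicate 1 (0.284) and 6 h replicates 2 (0.0587) and 3 (0.118).

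Immediate early genes were higher 2 h after tunicamycin, with a median of 1.10 in RNA-Seq (0 called, 5 adjusted over the list alone, adjusted p = 9.22e-20, adjusted p = 0.174 with an estimated correlation). Extra reads of untreated replicate 1 were argued against, since the median was 1.11 without that library. A difference between the replicates stays open: against the mean of the untreated libraries, the tunicamycin libraries had median log2 ratios of -0.45, 1.52 and 2.14 in RNA-Seq, and the untreated libraries -0.89, 0.17 and 0.63. In Ribo-Seq, where the numbers pair, those of the same-numbered pairs were 0.04, 0.24 and 1.43. Handling of the cultures, such as a change of medium, could act on these genes too, and no vehicle library of 2 h was used here with which to test it. An effect of tunicamycin also stays open.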

How the results depend on the processing

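Counts of called genes are given in the order tunicamycin 2 h, tunicamycin 6 h, 6 h against 2 h, thapsigargin 2 h, thapsigargin 6 h, and thapsigargin against tunicamycin at 2 h and 6 h, against 4, 617, 305, 41, 737, 11 and 0 in RNA-Seq and 0, 163, 146, 16, 189, 5 and 4 in Ribo-Seq. Alternatives chosen after seeing the data are named in the methods. Where a count moved, the cause was not tested. In RNA-Seq, DESeq2's size factors in edgeR gave 4, 617, 309, 38, 747, 0 and 0. Library size alone gave 4, 416, 225, 20, 414, 0 and 0, no filter 6, 684, 349, 61, 750, 13 and 24, and a minimum count of 50 gave 4, 799, 457, 45, 1113, 0 and 0. DESeq2 gave 68, 2485, 1583, 770, 3528, 250 and 375. The replicate block gave 8, 1624, 1121, 247, 1437, 13 and 29, and kept 612 of the 617 genes and 5 of the 11 of thapsigargin against tunicamycin at 2 h. The compared groups alone gave 2, 434, 737, 0, 0, 0 and 0, and the filter on the 3-library groups 4, 786, 432, 40, 1103, 0 and 0. The block without untreated replicate 1 gave 791, 7439, 10303, 3995, 8333, 4057 and 4211, and replicates 2 and 3 alone gave 1269, 5590 and 7230 for the first 3. Leaving out 1 library gave 4 to 7, 187 to 963, 23 to 223, 7 to 107, 178 to 2411, 0 and 0. Replicate numbers of untreated cells and tunicamycin 2 h in RNA-Seq had correlations of 0.172, 0.0757 and 0.238, so the numbers were not read as pairs there, although every library correlated best with its own number.

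In Ribo-Seq, DESeq2's size factors gave 0, 169, 166, 16, 219, 5 and 4, and library size alone 0, 150, 125, 17, 219, 8 and 6. No filter gave 47, 745, 495, 189, 731, 139 and 213, and a minimum count of 50 gave 0, 189, 187, 16, 239, 3 and 1. DESeq2 gave 3, 686, 526, 190, 1046, 116 and 200, and the compared groups alone 0, 176, 137, 0, 0, 0 and 43. The filter on the 3-library groups gave 0, 175, 158, 16, 210, 5 and 2. The replicate block gave 0, 386 and 364 for the first 3, the block without untreated replicate 1 gave 0, 651 and 1614, and replicates 2 and 3 alone 0, 378 and 639. Leaving out 1 library gave 0, 34 to 166, 30 to 162, 3 to 26, 63 to 300, 0 to 2 and 0 to 1. For translational efficiency (tunicamycin 2 h and 6 h, thapsigargin 2 h and 6 h, against 0, 0, 1 and 0), DESeq2 gave 14, 20, 58 and 119, separate fits 2, 0, 13 and 26, voom 0, 0, 1 (not SNORD71) and 1, no filter 0, 0, 1 and 1, the compared groups alone 0, 0, 0 and 0, and no untreated replicate 1 of either assay 0, 0, 2 and 0. Leaving out 1 library gave 0, 0, 1 to 3 and 0 to 1.

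Of the gene lists (2 h, 6 h, 6 h against 2 h), 18, 14 and 16 passed in RNA-Seq and 1, 8 and 2 with an estimated correlation, and in Ribo-Seq 8, 14 and 14, and 0, 6 and 7 with an estimated correlation. Leaving out 1 library gave 12 to 21, 12 to 16 and 14 to 19 in RNA-Seq and 5 to 9, 11 to 15 and 13 to 18 in Ribo-Seq, with 5 without Ribo-Seq untreated replicate 1. For translational efficiency 6 and 5 lists passed, 0 and 0 with an estimated correlation, 2 and 1 with DESeq2's size factors, 7 and 1 with library size alone, 1 and 0 with no untreated replicate 1 of either assay, 7 and 1 with replicates 2 and 3 alone, and 0 to 12 and 1 to 11 when 1 library was left out. The correlation between the drugs over genes with a mean of at least 50 counts was 0.635 and 0.731 in RNA-Seq and 0.596 and 0.639 in Ribo-Seq (2 h and 6 h). Leaving out 1 untreated library gave 0.567 to 0.837 and 0.699 to 0.846 in RNA-Seq, and 0.323 to 0.468 and 0.377 to 0.493 in Ribo-Seq. The first 4 values have no simulated value beside them and are not read as agreement.

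Over the named genes 2512 values under alternatives kept their direction and side of the threshold, 428 no longer passed, 46 came to pass and 7 reversed. All 7 were footprints at 2 h of tunicamycin that had not passed: DNAJB9 log2 fold change was 0.0460 without Ribo-Seq untreated replicate 1 (-0.83 to 0.0460 when 1 library was left out), 0.19 with the block and without it, and 0.21 with replicates 2 and 3 alone, PSAT1 -0.11 without tunicamycin 2 h replicate 1 (-0.11 to 0.44 when 1 library was left out), -0.00710 with the block without untreated replicate 1 and -0.0737 with replicates 2 and 3 alone, and MTHFD2 -0.0220 with the last. HERPUD1 at 2 h in RNA-Seq, DDIT3, HERPUD1, HSPA5, DNAJB9, XBP1 and TRIB3 at 6 h in RNA-Seq and DDIT3, HERPUD1, TRIB3, DNAJB9 and HSPA5 at 6 h in Ribo-Seq passed in every alternative run. With the thapsigargin groups fitted alone no sentinel gene passed.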

Other observations

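The tests of a batch shared with replicate 1 and of the mitochondrially encoded share were chosen after the result was seen, and the tests of untreated replicate 1 and of other splits were set before. Ribosomal protein mRNAs were higher under thapsigargin than under tunicamycin at 6 h, by a median of 0.41 in footprints (79 genes, 0 called by either adjustment, adjusted p = 1.77e-06) and 0.37 in RNA (0.00042), with adjusted p = 0.861 and 0.883 with an estimated correlation. Cholesterol synthesis genes were higher under thapsigargin at 6 h than in untreated cells, where 3 of 24 rose in RNA (8 adjusted over the list alone, median 0.44, adjusted p = 1.23e-05 and, with an estimated correlation, 0.18). Each rests on 1 thapsigargin library.

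RNA-Seq untreated replicate 1 had counts in more genes than the other RNA-Seq libraries. Greater depth was argued against, since 52919 genes still had counts after thinning to the smallest total. RNA of another cell type was argued against as well, since the top 1% of the otherwise near-silent genes held 9.14% of their counts there, where a few abundant transcripts would hold most. Genomic DNA in the library is a candidate explanation, since 68.7% of olfactory receptor genes had at least 10 counts.

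The thapsigargin libraries stood apart from tunicamycin replicates 2 and 3. Whether thapsigargin lowered the mitochondrially encoded share stays open. In RNA-Seq the thapsigargin libraries lay above tunicamycin replicate 1, by 0.144 percentage points at 2 h and 0.0131 at 6 h, and untreated replicate 1 was at 1.06%. In Ribo-Seq they lay below it, at 1.38 against 3.40% at 2 h and 1.64 against 2.78% at 6 h. A batch shared with replicate 1 is a candidate explanation: across genes, thapsigargin at 2 h minus tunicamycin replicates 2 and 3 correlated with tunicamycin 6 h replicate 1 minus its replicates 2 and 3 at r = 0.518 in RNA-Seq, with no shared library. The other way round r was 0.527, and in Ribo-Seq it was 0.287 and 0.169. With 1 library per time, an effect of thapsigargin and this batch cannot be separated, against tunicamycin or untreated cells. No untreated RNA-Seq library shared the second component of thapsigargin.

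The counts of called genes were set against other splits of the same libraries, fitted on the compared groups alone. The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. In RNA-Seq the real split, 1 of 10, called 2, 434 and 737 genes (2 h, 6 h, and 6 h against 2 h), and the highest other split called 0 each time. In Ribo-Seq it called 176 at 6 h and 137 for 6 h against 2 h, where the highest other called 1 and 2, and 0 at 2 h, where the highest other called 2. For translational efficiency 100 splits were drawn at each time. The real split called 0 genes there, as in Ribo-Seq at 2 h, so that all 100 (or all 10) call at least as many by construction, and nothing about chance follows. The highest other split called 1 at 2 h and 2195 at 6 h. The latter exchanged the labels in RNA-Seq alone and so tested the sum of the RNA and footprint changes.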
